A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

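RNA was measured by sequencing in 2 strains of the budding yeast Saccharomyces cerevisiae, MF02, which the labels call wild type, and UV02_HG. Both were grown in medium with 40% (w/v) glucose and sampled in mid-exponential phase. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a NEBNext Ultra kit and sequencing was done on an Illumina HiSeq instrument. The submitters' processing notes list Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1. The genome build and the strand setting of the counting are not given in the sources used here.

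The authors deposited FPKM values, that is, fragments scaled by the length of the gene model and by library size, for 7163 features. Per the file headers there are 2 FPKM columns per strain. The labels give 1 sample per strain, so the columns were treated as runs of 1 sample, and the strain value is their mean. The series design speaks of duplicates, but nothing in the labels says whether the columns came from separate cultures. Each strain therefore counted as 1 replicate, single genes are given with column values, with the range of the fold over the 4 column comparisons or with a log2 ratio of the column means, and no p-value was computed. A further 4 rows without values were not analysed here.

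Identifiers were matched to locus tags of the R64 annotation (NCBI RefSeq), which gave names, chromosomes and neighbour order. Of the features, 6045 matched and 6010 had a coding length there. Because the authors' build is not named, no coordinates are printed. Multiplying FPKM by the R64 coding length gave whole numbers of reads, within 0.02, for 99.9% of 5782 genes in MF02 column 1 and 99.8% in each of the other columns. The library totals that give these whole numbers were 12796339 and 15144991 reads in MF02 and 12507299 and 13040931 reads in UV02_HG. At these depths a gene of 10 FPKM and 1000 nt had 128, 151, 125 and 130 reads. Some genes named had far fewer, such as EMA17 with 1 and 0 in MF02 and PAU7 with 9 and 6 in UV02_HG. Counting intervals and floors cover counting error only. A count-based test was not run on the recovered reads, since there was 1 sample per strain.

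Ratios are log2((FPKM + 1) of UV02_HG / (FPKM + 1) of MF02), which understates differences of weakly expressed genes. Such genes can thereby stand above genes of the same length whose ratios are negative. The features with at least 1 FPKM in either strain were kept (6291, of which 5695 had a coding length). A 2-fold difference means a log2 ratio of at least 1 in size. Before the data were examined, 44 gene lists were fixed, and a list was summarised when 3 or more members were expressed. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 10 classes. Chromosome medians were placed among 10000 random gene sets of the same size. Chosen after seeing the data were the values relative to genes of the same coding length (the ratio minus the running median of the 201 genes nearest in length), the random lists matched on 10 length classes with 4 expression classes in each, the same adjustment followed by one for GC content, the use of single columns, and the restriction to protein-coding genes.

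The genes named were set by a rule fixed beforehand. Among genes with at least 10 FPKM in either strain it takes the 12 with the largest positive and the 12 with the largest negative ratio. It also takes up to 4 members per list with the largest ratio in size, and any measured member of the glycolysis, hexose transport, glycerol, trehalose and ethanol fermentation lists. Names outside the rule are marked where they appear. The alternatives set beforehand were pseudocounts of 0.1 and 5, rescaling to equal FPKM totals (TPM), upper quartile scaling, centring on the median gene, trimmed mean of M values scaling (trims of 30% and 5%), 3 other filters, fold thresholds of 1.5 and 4, list means, and summed near-identical copies.

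The statistics were tested on simulated reads for 5663 genes of the UV02_HG and MF02 comparison, with a length trend between the strains planted. After the length adjustment, 99.0% of 97 genes planted at a log2 change of 2 and 84.8% of 99 genes planted at 1.5 passed 2-fold in the right direction, and 0.458% of 5244 unchanged genes did so. Without the adjustment 40.6% of the unchanged genes passed. The simulated columns of each strain had the same length trend and equal noise, whereas the MF02 columns in the data differed by length. These rates therefore do not measure the error in the data. A list of 26 genes planted at a log2 change of 1 came out at percentile 100, while 4 of 42 other lists fell outside the central 95% of random lists. A chromosome shift planted on 203 genes was recovered at 0.40, and 1 of the other 15 chromosomes fell outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.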

Results

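The data are FPKM values of 2 yeast strains, MF02 and UV02_HG, grown at 40% glucose, with 1 sample and 2 columns of values per strain. The series title speaks of a strain tolerant to high glucose, and the design implies 1 comparison, UV02_HG against MF02. The columns rested on 12796339 and 15144991 counted reads in MF02 and 12507299 and 13040931 in UV02_HG. With 1 sample per strain there is no replicate check of any difference below, and the spread between columns may be technical.

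Genes for making and importing thiamine (vitamin B1) were far lower in UV02_HG, with a list median log2 ratio of -3.50 (-4.04 to -2.50 over the 4 comparisons of single columns). Heat shock proteins and chaperones were lower too, with a median of -3.11 (-3.66 to -2.10). Relative to genes of the same length, these medians were -2.14 and -1.64. All 17 measured glycolysis genes were at least 2-fold lower in UV02_HG, 11 of them after centring on the median gene and 7 relative to genes of the same length. Their list lay inside the central 95% of random lists matched on length and expression. Its median relative to genes of the same length stood at percentile 0.465 of lists matched on expression, outside the central 95%. The hexose transporter genes HXT1 and HXT4, both on chromosome VIII, were 12.1-fold and 9.88-fold lower, at log2 ratios of -2.12 and -1.75 relative to genes of the same length. Ribosomal protein genes, with a median of 0.99 (0.36 to 1.35), and small nucleolar RNAs, with a median of 2.62 (2.16 to 3.22), were higher in UV02_HG, although the ribosomal protein median fell to -0.10 when columns were rescaled to equal FPKM totals. The small nucleolar RNAs have no coding length and could not be set against genes of the same length. Among genes of like length, those of sulfur and methionine metabolism stood highest of the larger lists, with MET14 8.90-fold higher. Genes of chromosome XIII were higher as a group than those of the other chromosomes.

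Of 6291 expressed features, 927 were at least 2-fold higher and 2967 at least 2-fold lower in UV02_HG. The median ratio of all of them was -0.89 on the log2 scale, and differences are best read relative to it. Scaling moved that median by -0.93 (equal FPKM totals), 0.63 (upper quartile), 0.89 (centring on the median gene) and 0.77 (trimmed mean of M values). The share of higher genes among those past 2-fold was 23.8% as deposited, and 6.43%, 46.5%, 58.1% and 53.4% under these scalings in the same order. In all 4 comparisons of a UV02_HG column with an MF02 column, 546 features were at least 2-fold higher and 1568 at least 2-fold lower.

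The ratio between the strains followed gene length. Its median was 1.25 in the 271 genes with coding lengths up to 300 nt, -0.14 between 501 and 750 nt, and -1.68 in the 76 genes longer than 5000 nt. Across genes, which are not independent replicates, Spearman's rho of length with the strain ratio was -0.53. The columns of MF02 also differed by length, with a rho of 0.62 for column 2 over column 1, whereas the UV02_HG columns gave 0.07. MF02 column 2 was at least 2-fold above column 1 for 1760 features and below it for 640 (Pearson's r = 0.92), and in UV02_HG these numbers were 238 and 271 (r = 0.98). Relative to genes of the same coding length, 971 genes were at least 2-fold higher and 955 lower, and 358 and 829 genes met both definitions. Each gene group below is therefore given with its median relative to genes of the same length, called the length-relative median, and the percentile of its raw median among random lists matched on length and expression. Percentiles of the length-relative median itself, or of the median relative to length and GC content, among lists matched on expression are added where the central 95% holds one and not another. Folds of single genes are raw, so the length trend is part of them. They are followed by their range over the 4 column comparisons, and so are raw list medians that a column comparison moves by over 1.5 times. With MF02 column 1 alone, 27 of the 90 named genes past 2-fold moved by over 1.5 times, 26 of them to a smaller difference, and with MF02 column 2, UV02_HG column 1 and UV02_HG column 2 alone 27, 13 and 7 genes moved so far.

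**Figure D1:**
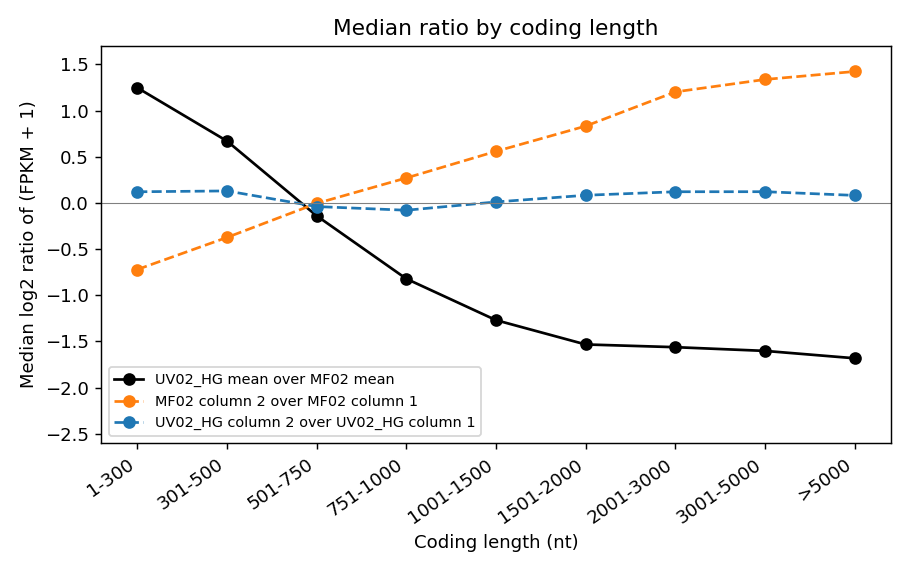
Median log2 ratio of (FPKM + 1) in 9 classes of coding length, for the strain means (black) and for the 2 columns of MF02 (orange) and of UV02_HG (blue). The strain ratio runs from 1.25 in the shortest to -1.68 in the longest genes, the MF02 columns differ from -0.72 to 1.42, and the UV02_HG columns stay between -0.08 and 0.13.

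The genes with the largest deficits in UV02_HG belonged mostly to thiamine and vitamin B6 metabolism. THI11 (YJR156C), THI13 (YDL244W), THI12 (YNL332W) and THI5 (YFL058W), near-identical genes for synthesis of the pyrimidine part of thiamine, were 158-fold (110 to 271), 99.3-fold (50.2 to 352), 94.4-fold (55.7 to 227) and 59.6-fold (31.0 to 182) lower. Their reads may be split among the copies. THI11 stood at 4374 and 4124 FPKM in MF02 and at 36.6 and 15.1 FPKM in UV02_HG. THI22 (42.2-fold, 18.7 to 68.8), the thiamine transporter gene THI72 (25.2-fold, 10.6 to 42.0) and the vitamin B6 genes SNZ2 (32.8-fold, 29.7 to 36.5) and SNZ3 (log2 ratio -4.58) were lower as well. THI4, which encodes the thiazole synthase and was named after its values were seen, had 13611 and 11484 FPKM in MF02 and 919 and 367 FPKM in UV02_HG. Of 24 list members, 21 were at least 2-fold lower (17 relative to length) and 0 higher, and the vitamin B6 gene SNZ1 was named after its value was seen because its log2 ratio, -0.14, lay near 0. The length-relative median was -2.14, and none of 10000 matched random lists had so low a median (percentile 0).

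The other genes among the 12 lowest were GIT1, a glycerophosphoinositol transporter gene (32.4-fold lower, 14.5 to 55.6), BRE5, a deubiquitination cofactor gene (27.9-fold, 8.51 to 47.8), ULI1 (27.0-fold, 22.3 to 32.5) and YHR175W-A. The last had 25.5 and 47.5 FPKM in MF02 and 0 reads in UV02_HG, at least 23.3-fold lower against a floor of 3 reads per column. At the other end, EMA17 (YIL029C, chromosome IX) had 1 read in MF02 against 1009 in UV02_HG, a ratio of 1104 corrected for the library totals, with an exact 95% counting interval from 198 to 43629. RDL1, a thiosulfate sulfurtransferase gene (14.7-fold, 7.66 to 34.96), RPL35A (14.5-fold, 9.91 to 22.5) and YNL277W-A (19.1-fold, 9.92 to 47.8) were the other protein-coding genes among the 12 highest. The rest were the small nucleolar RNAs snR49 (14.8-fold, 8.19 to 38.2), snR67 (14.6-fold, 8.84 to 30.1), snR40 (14.4-fold, 9.30 to 25.04) and snR13 (14.2-fold, 9.71 to 24.96) and the transfer RNA genes tV(AAC)M1 (34.8-fold, 28.4 to 42.1), tI(AAU)G (14.2-fold, 8.55 to 25.9), tF(GAA)D and tR(UCU)B. The last pair was listed at 0 in MF02 and averaged 44.7 and 15.7 FPKM in UV02_HG. Transfer RNA copies may share reads, so single loci are uncertain. As classes, 76 of 78 expressed small nucleolar and nuclear RNAs were at least 2-fold higher, as were 143 transfer RNA features, with 5 lower and a median of 1.4997 (1.07 to 2.16). Transfer RNAs and most small nucleolar RNAs are short, and they have no coding length, so their ratios were not set against genes of the same length.

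**Figure D2:**
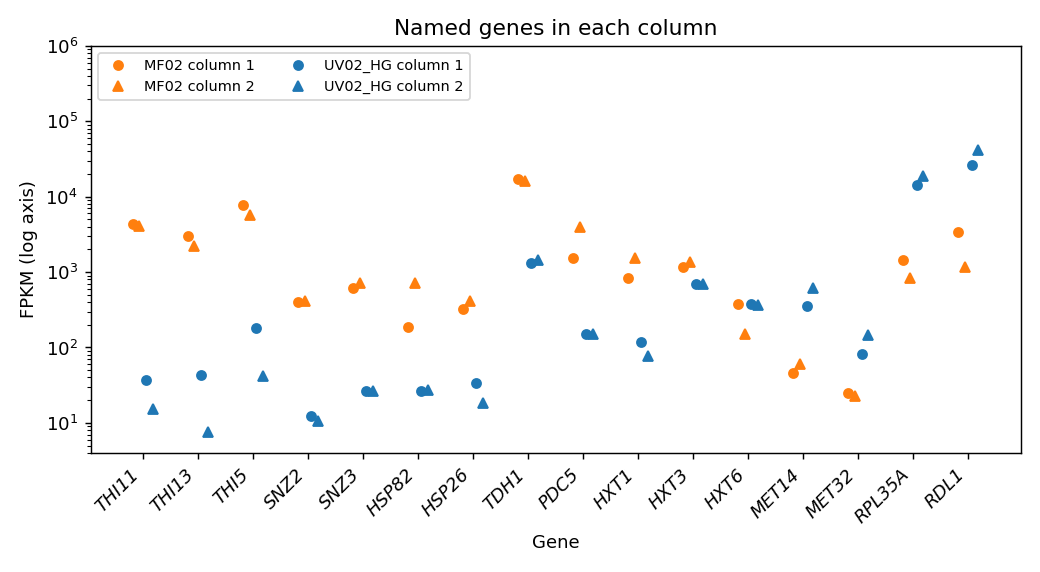
FPKM (log axis) of 16 named genes in each of the 4 columns, MF02 in orange and UV02_HG in blue, circles for column 1 and triangles for column 2. THI11 lies at 4374 and 4124 FPKM in MF02 and at 36.6 and 15.1 FPKM in UV02_HG, and MET14 and RPL35A lie higher in UV02_HG in both columns.

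Protein folding genes were lower in UV02_HG. Of 28 heat shock proteins and chaperones 25 were at least 2-fold lower (24 relative to length), with a length-relative median of -1.64 (percentile 0). The examples are HSP82, the inducible Hsp90 gene (16.1-fold, 6.77 to 25.5), the mitochondrial disaggregase gene HSP78 (13.9-fold, 5.60 to 23.99), the small heat shock gene HSP26 (13.7-fold, 9.39 to 21.6) and SSB1 (11.6-fold, 5.25 to 37.9), which may share reads with its near-identical copy. The 2 members that were at least 2-fold higher, HSP12 (log2 ratio 2.16) and HSP10 (1.695), are short genes and were named after their values were seen. Relative to length, 1 of the 28 members was at least 2-fold higher. Genes for folding in the endoplasmic reticulum had a median of -2.30 (-2.57 to -1.71) and a length-relative median of -0.84 (percentile 0.02). Of the 18 members 14 were at least 2-fold lower (8 at least 2-fold lower relative to length). Among them were SIL1 (10.3-fold, 5.87 to 15.4), the thiol oxidase gene ERO1 (10.2-fold, 3.66 to 18.1) and KAR2 (8.82-fold, 3.59 to 15.4), the BiP chaperone gene. Proteasome and ubiquitin genes had a median of -1.67 and a length-relative median of -0.74 (percentile 1.25), with RPN1 10.2-fold (4.97 to 16.5) lower.

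In central carbon metabolism the glycolysis list had a median of -2.004, with the glyceraldehyde phosphate dehydrogenase gene TDH1 12.1-fold (11.2 to 13.1), the pyruvate kinase gene CDC19 10.8-fold (6.51 to 20.3) and PFK1 8.57-fold (2.96 to 15.7) lower. PGK1 (2.48-fold lower, 1.74 to 4.02) and GLK1 (2.06-fold lower) differed less, and GLK1 ran from -2.40 to 0.50 on the log2 scale over the column comparisons and was level with MF02 column 2 alone (0.00807). GLK1 turned to 0.35 relative to length. Relative to length and GC content, GLK1 turned to 0.65 and PGK1 to 0.53. The length-relative median of glycolysis was -0.83, and its length-matched percentile, 3.96, was inside the central 95%, while the length-relative median itself stood at percentile 0.465 and that relative to length and GC content at 1.255. Ethanol fermentation genes had a median of -1.71, a length-relative median of -0.43 and percentile 24.98. In this list the pyruvate decarboxylase gene PDC5 was 18.0-fold (9.99 to 26.0) lower, while the log2 ratios of PDC1 (-0.71), ADH1 (-0.22) and ADH2 (-0.29) turned positive under centring on the median gene. The tricarboxylic acid cycle (median -1.41, length-relative -0.37, percentile 49.8) and the pentose phosphate pathway (-1.54, -0.45 and 17.3) lay inside the central 95% of length-matched lists. So did acetate and aldehyde metabolism (-0.83, 0.69 and 97.1, with 93.7 relative to length and 98.7 relative to length and GC content), whose raw median turned positive under centring on the median gene.

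Hexose transporter genes parted by member. HXT1 had 847 and 1552 FPKM in MF02 and 119 and 78.1 FPKM in UV02_HG, and HXT4 had 922 and 518 against 58.7 and 85.3 FPKM. The log2 ratios of HXT3 (-0.88), HXT2 (-0.59), HXT7 (-0.01) and HXT6 (0.49) changed sign under 1 or more scalings, and HXT6 and HXT7 may share reads as near-identical copies. Relative to length, HXT1 stood at -2.12, HXT4 at -1.75 and HXT3 at 0.60. HXT1, HXT4 and HXT5 (-0.43 relative to length) lie on chromosome VIII, whose length-relative median was -0.34, and HXT3 lies on chromosome IV. Whether the low values of HXT1 and HXT4 belong to their region or to the single genes was not tested. The list's median was -0.60, positive after centring on the median gene (0.29), with a length-relative median of 0.89 (percentile 99.7). Glucose sensing and repression genes had a median of -1.91 (-2.49 to -1.34) and a length-relative median of -0.32 (percentile 2.62), including the repressor genes TUP1 (8.32-fold lower, 4.25 to 14.3) and MIG1 (8.29-fold lower, 5.33 to 12.5). Genes for other carbon sources stood high for their length, to which the pseudocount can add where they are weakly expressed. Gluconeogenesis and glyoxylate cycle genes had a median of -0.14 (-0.81 to 0.44) and a length-relative median of 1.01 (percentile 99.99), and galactose, sucrose and maltose genes had -0.68 and 0.86 (percentile 99.3). Their raw medians turned positive under centring on the median gene. Among random lists matched on expression alone, these raw medians stood at percentile 99.4 and 69.3. As deposited, 5 of the 17 gluconeogenesis genes were at least 2-fold lower and 2 higher. Upper quartile scaling, centring on the median gene and the trimmed mean of M values each gave 2 lower and 5 higher. Equal FPKM totals gave 9 lower and 0 higher, and relative to length 1 was lower and 9 were higher. The malate dehydrogenase gene MDH2 (8.09-fold, 5.66 to 13.7), the activator gene ADR1 (3.77-fold, 3.05 to 4.66) and the lactate permease gene JEN1 (2.55-fold, 1.45 to 3.73) were lower, and the activator gene SIP4, at a low level, was higher (2.57-fold, 2.14 to 3.06). Relative to length, the log2 ratios of these genes in this order were -1.67, -0.32, 0.0641 and 2.83, so JEN1 was no longer lower. Of the 16 galactose, sucrose and maltose genes 6 were at least 2-fold lower, with IMA5 (6.31-fold, 5.65 to 6.99), the invertase gene SUC2 (4.79-fold, 2.58 to 7.12) and the repressor gene GAL80 (3.16-fold, 2.39 to 4.04), and 1 was higher, the activator gene MAL33 (3.10-fold, 2.47 to 4.14), at a low level. Centring on the median gene gave 2 lower and 2 higher, the trimmed mean of M values 3 and 2, upper quartile scaling 4 and 2, and equal FPKM totals 11 and 0. Relative to length 1 was lower and 7 were higher. GAL80 turned to 0.0611 relative to length and GC content.

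Genes tied to osmotic stress lay inside the central 95% of length-matched lists. Glycerol metabolism had a median of -1.72 and a length-relative median of -0.38 (percentile 24.9), with the glycerol phosphatase gene GPP1 10.9-fold (4.17 to 19.5) and the glycerol phosphate dehydrogenase gene GPD1 5.19-fold (3.45 to 8.76) lower. Relative to length, GPP1 was at a log2 ratio of -2.91 and GPD1 at -0.97. STL1, a glycerol importer gene, had a log2 ratio of -0.69 that turned positive under centring on the median gene. The HOG pathway list gave -1.63 (-2.09 to -1.04) and -0.22 (percentile 19.3), and sodium, potassium and proton transport gave -1.45 and -0.25 (percentile 25), with the proton pump gene PMA1 17.0-fold (5.76 to 31.8) lower and at a log2 ratio of -2.53 relative to length. Trehalose metabolism had a median of -1.71 and a length-relative median of -0.13 (percentile 53.3). Within it, NTH1 (8.59-fold, 5.98 to 11.3) and TPS1 (5.18-fold, 3.14 to 10.4) were lower and ATH1 had a ratio of -0.11, positive after centring on the median gene. Relative to length, NTH1 was at a log2 ratio of -1.47 and TPS1 at -0.88. Glycogen metabolism gave -1.58 and -0.14 (percentile 61.1).

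Sulfur and methionine metabolism had a median of -0.02 against -0.89 for all genes, and 27 of 30 members lay above genes of the same length. Its length-relative median was 1.33 (percentile 100), and the raw median was positive under 3 of the 4 scalings. MET14, the adenylylsulfate kinase gene, had 46.3 and 60.9 FPKM in MF02 and 359 and 611 FPKM in UV02_HG, and the regulator gene MET32 was 4.63-fold (3.16 to 6.24) higher. The S-adenosylmethionine synthetase gene SAM2 (6.36-fold, 3.87 to 9.66) and the cystathionine synthase gene CYS4 (4.80-fold, 2.53 to 8.48) were lower. General amino acid synthesis had a median of -1.90 and a length-relative median of -0.54 (percentile 0.25, and 6.89 relative to length and GC content). Of its 48 genes 38 were at least 2-fold lower (11 at least 2-fold lower relative to length), among them ARG1 (17.6-fold, 14.2 to 21.5) and BAT2 (11.3-fold, 7.55 to 16.4). Nitrogen catabolite repression genes gave -1.84 and -0.43 (percentile 4.04, and 2.24 relative to length), with the urea amidolyase gene DUR1,2 18.9-fold (7.30 to 33.1) and the ammonium permease gene MEP2 16.0-fold (15.7 to 16.2) lower. Phosphate starvation genes gave -1.13 and -0.42 (percentile 43.0).

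Of 138 cytosolic ribosomal protein genes, 68 were at least 2-fold higher and 20 lower, against 25 and 40 with equal FPKM totals and 47 and 20 relative to length. Their raw median stood at percentile 99.3 of length-matched lists, and at 96.5 and 93.5 of expression-matched lists with MF02 column 2 or UV02_HG column 2 alone. Their length-relative median was 0.36 (percentile 92.4 of expression-matched lists, inside the central 95%, but 99.96 relative to length and GC content), and many of them are near-identical pairs that may share reads. RPL9A (9.05-fold, 7.38 to 11.1) and RPS31 (8.86-fold, 5.22 to 22.8) were among the highest. Ribosome biogenesis genes, which are longer, gave -1.14 (-1.88 to -0.13) and 0.06 (percentile 83.1). Respiratory chain and ATP synthase genes had a median of 0.50, negative with equal FPKM totals (-0.59), and a length-relative median of 0.19 (percentile 50.4). Within this list the short genes COX7 (8.14-fold, 4.998 to 15.1) and ATP17 (6.12-fold, 3.78 to 12.4) were higher and the longer ATP2 (5.47-fold, 4.08 to 8.12) and ATP3 (5.38-fold, 4.74 to 6.05) lower. The cell cycle and histone list had a median of -1.35 (-1.83 to -0.69) and a length-relative median of -0.12 (percentile 4.36). The histone genes HTA2 (9.68-fold, 6.07 to 14.6), HHF2 (9.33-fold, 5.08 to 13.7), HTA1 (9.27-fold, 5.55 to 24.04) and HHF1 (9.23-fold, 3.60 to 20.1), all short and with near-identical copies, were higher.

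Lists expressed at low levels had their ratios compressed toward 0 by the pseudocount, which can place them above genes of the same length with negative ratios. Haploid and mating type genes had a median of 0.27, negative with equal FPKM totals (-0.72), and a length-relative median of 1.02 (percentile 100), with PRM1 (2.82-fold, 2.003 to 4.06) and FUS3 (2.75-fold, 1.59 to 6.52) higher and MF(ALPHA)2 2.63-fold (1.44 to 4.65) lower. Meiosis and sporulation genes gave -0.27, positive under 3 of the 4 scalings, and 0.70 (percentile 99.95, and 97.1 relative to length and GC content). Their raw median stood at percentile 76.8 of lists matched on expression alone. The 5 expressed genes of the mitochondrial genome gave 0.99 (0.33 to 1.62) and 1.91 (percentile 99.4), with OLI1, an ATP synthase subunit gene, 9.18-fold (4.15 to 23.3) higher. Of 4 genes that many non-S288C strains lack, 0 reached 1 FPKM. Flocculation and aquaporin genes gave -0.48, positive under 3 of the 4 scalings, and 0.83 (percentile 95.8, and 99.8 relative to length and GC content). Matched on expression alone, their raw median stood at percentile 73.0.

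**Figure D3:**
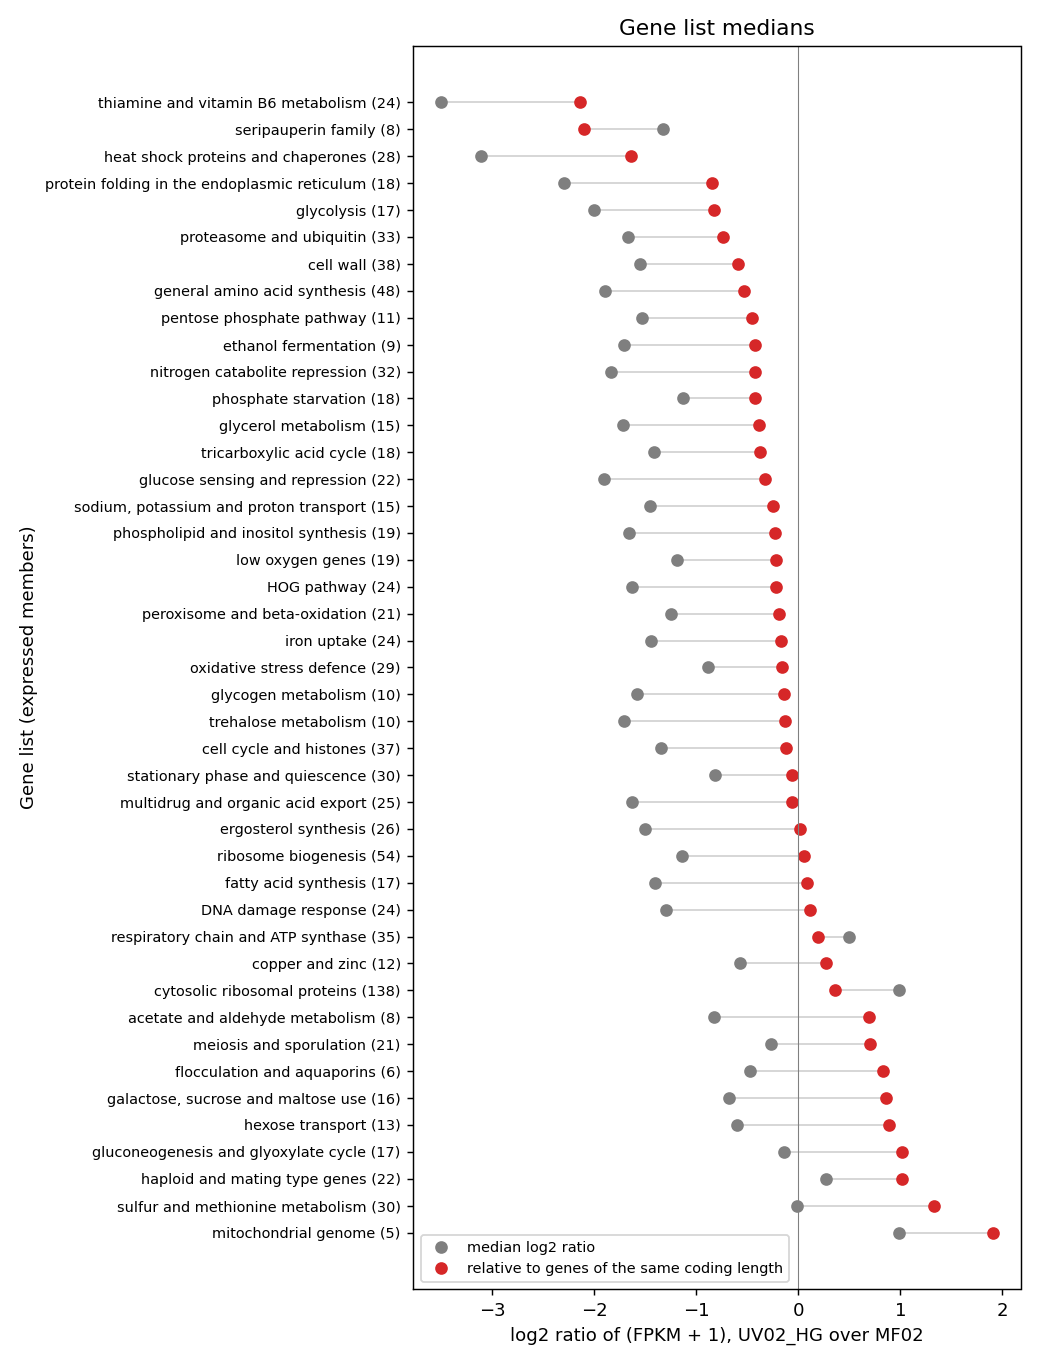
Median log2 ratio of UV02_HG over MF02 for 43 gene lists, as deposited (grey) and relative to genes of the same coding length (red), with the number of expressed members in parentheses. Thiamine, seripauperin and chaperone genes lie lowest and mitochondrial genome, sulfur and mating genes highest relative to length, at -2.14, -2.10, -1.64, 1.91, 1.33 and 1.02.

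Among lists of the cell surface, lipids and metals, the seripauperin family stood low for its short genes. Its median was -1.33 and its length-relative median -2.10 (percentile 0.06), over 8 expressed near-identical members such as PAU7 (6.94-fold lower, 3.62 to 11.6). Cell wall genes gave -1.55 and -0.59 (percentile 7.12, and 0.10 relative to length), with the glucan synthase gene GSC2 (13.0-fold, 6.88 to 19.1) and the kinase gene SLT2 (10.2-fold, 6.29 to 15.5) lower. Ergosterol synthesis gave -1.4997 (-1.83 to -0.79) and 0.02 (percentile 38.0), fatty acid synthesis -1.41 and 0.08 (percentile 60.8), and phospholipid and inositol synthesis -1.66 and -0.23 (percentile 15.1), with INO1 8.17-fold (6.07 to 10.6) lower. Low oxygen genes gave -1.19 and -0.22 (percentile 16.2). Iron uptake genes gave -1.45 and -0.17 (percentile 20.9), with the siderophore transporter gene ARN1 17.6-fold (10.003 to 27.0) lower. Copper and zinc genes gave -0.57, positive under 3 of the 4 scalings, and 0.27 (percentile 77.7). As deposited, 5 of the 12 genes were at least 2-fold lower and 1 higher. Those 3 scalings each gave 2 lower and 3 higher, and equal FPKM totals gave 9 lower and 0 higher. Relative to length 1 was lower and 3 were higher. ZRT3 (4.32-fold, 3.28 to 5.72), CTR2 (3.80-fold, 2.21 to 7.75) and CTR1 (3.14-fold, 2.17 to 4.29), metal transporter genes, were lower and the copper transporter gene CTR3 (2.31-fold, 1.22 to 4.34) higher. Multidrug and organic acid export gave -1.63 (-2.23 to -0.84) and -0.06 (percentile 45.005).

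The remaining lists lay inside the central 95% of length-matched lists. Oxidative stress defence gave -0.89 and -0.16 (percentile 7.65), and stationary phase and quiescence gave -0.82 and -0.06 (percentile 10.2), with YGP1 13.6-fold (7.50 to 22.1) lower, and both raw medians turned positive under centring on the median gene. DNA damage response gave -1.30 (-1.52 to -0.52) and 0.12 (percentile 63.5), and peroxisome and beta-oxidation gave -1.25 and -0.19 (percentile 57.8). Of the 43 lists summarised, 16 lay below and 4 above the central 95% of random lists matched on expression. Matched on length as well, these numbers were 6 and 8.

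Chromosome XIII stood above the other nuclear chromosomes. The median of its 456 genes was 0.36 above that of all genes on nuclear chromosomes (-1.04) on the log2 scale (percentile 100 of random gene sets) and 0.37 relative to genes of the same length, between 0.36 and 0.46 in the 4 column comparisons. All 15 of its blocks of 30 neighbouring genes had length-relative medians above 0, from 0.18 to 0.73. Chromosome VIII was the other one outside the central 95% of random sets, at -0.29 (percentile 0.08) and -0.34 relative to length, with 3 of its 8 blocks above 0. Its length-relative median ran from -0.33 to -0.24 in the 4 column comparisons, so the value from the strain means lay just outside that range. Its 20 neighbouring genes from GEP4 to SET1, a run chosen after the values were seen and named by its ends, had a length-relative median of -1.51, and 0 of 1000 shuffles of gene order gave so extreme a run on any chromosome. The shuffles mixed genes of all chromosomes, so the low level of chromosome VIII as a whole is part of this number.

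**Figure D4:**
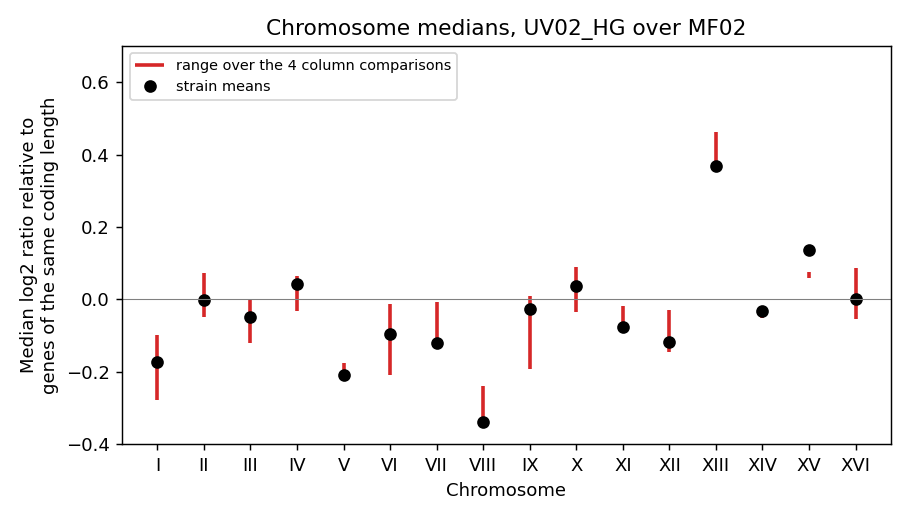
Median log2 ratio of UV02_HG over MF02 per nuclear chromosome, relative to genes of the same coding length, with points for the strain means and bars for the range over the 4 column comparisons. Chromosome XIII lies at 0.37 and chromosome VIII at -0.34.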

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

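The length, GC, single-column, protein-coding and length-matched settings were chosen after seeing the data, the others before. The cause of a move was not tested unless stated. The gene counts followed the scaling, which shifts all ratios together. Against 927 higher and 2967 lower genes, equal FPKM totals gave 296 higher and 4307 lower, upper quartile scaling 1496 higher and 1722 lower, centring on the median gene 1797 and 1296, and the trimmed mean of M values 1642 and 1431. A fold threshold of 4, stricter by construction, gave 307 higher and 1118 lower, and protein-coding genes alone gave 609 higher. Relative to genes of the same length 955 were lower, and 772 after a GC adjustment as well. Of the 24 largest differences, 11 stayed among the 24 largest relative to length and 12 relative to length and GC content, where features without a coding length drop out, and 16 or more did so under each other setting. Against 16 lists below and 4 above the central 95% of random lists, list means gave 26 below, values relative to length gave 9 below and 7 above, those relative to length and GC content 7 below and 9 above, length-matched random lists 6 below and 8 above, and UV02_HG column 2 alone 2 above. Thiamine and chaperone lists stayed at percentile 0 in every setting run. Ribosomal proteins left the top 2.5% with MF02 column 2 alone (percentile 96.5), UV02_HG column 2 alone (93.5) and relative to length (92.4). Against 2 chromosomes outside the central 95%, there were 4 with no filter, 6 relative to length, 4 relative to length and GC content and 5 with MF02 column 1 alone. Chromosome XIII, at 0.36 above all genes on nuclear chromosomes, moved to 0.43 and 0.31 with pseudocounts of 0.1 and 5, to 0.40 with upper quartile scaling, to 0.48 and 0.42 with stricter filters (10 FPKM in either strain, 1 FPKM in both), and to 0.41 and 0.42 with MF02 column 2 or UV02_HG column 1 alone. Chromosome VIII moved from -0.29 to -0.18 with a pseudocount of 5 and -0.20 with MF02 column 2 alone. Of 43 list medians 13 changed sign under 1 or more scalings, 9 of them in lists inside the central 95% of random lists. Those outside it that turned sign under any setting were ribosomal proteins (-0.10) and mating type genes (-0.72) with equal FPKM totals, ergosterol synthesis relative to length (0.0157) and to length and GC content (0.23), and cell cycle and histones relative to length and GC content (0.0501). Gluconeogenesis, at -0.14, became 0.50, 0.75 and 0.60 with upper quartile, centring and trimmed mean scaling, 1.01 relative to length, 1.31 relative to length and GC content and 0.27 with MF02 column 2 alone. Sulfur and methionine genes, at -0.02, became 0.60, 0.87 and 0.74 under those scalings, 0.12 as a list mean, 1.33 relative to length, 1.60 relative to length and GC content, and 0.0454, 0.00226 and 0.0250 with MF02 column 1, MF02 column 2 or UV02_HG column 2 alone. GLK1 became 0.35 relative to length, 0.65 relative to length and GC content and 0.00807 with MF02 column 2 alone, PGK1 0.53 relative to length and GC content, GAL80 0.0611 relative to length and GC content, and JEN1 0.0641 relative to length and 0.23 relative to length and GC content. Of the other list medians under the alternatives, 499 stayed within the spread between column comparisons and 296 moved beyond it. Of the other values of named genes, 1096 stayed within that spread and 481 moved beyond it without a change of sign from a 2-fold difference. No paired analysis was possible because each strain has 1 sample and no test was run.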

Other observations

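The tests below were chosen after the results were seen, apart from those of short abundant genes and of GC content for the length trend and of copy number for chromosome XIII.

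A few genes were nearly silent in one strain. The neighbours AIF1 (YNR074C) and COS10 (YNR075W), named after their values were seen, had 0 and 0.06 and 0 and 0 FPKM in the MF02 columns, against 13.5 and 7.69 and 6.33 and 9.27 FPKM in UV02_HG. After the length adjustment, chromosomes V (-0.21, percentile 0.215), VII (-0.12, percentile 1.41) and XII (-0.12, percentile 1.96) also lay low and XV (0.14, percentile 99.7) high. Over the 4 column comparisons these medians ran from -0.220 to -0.176, -0.129 to -0.00590, -0.146 to -0.0292 and 0.0590 to 0.0766. For chromosome XV the value from the strain means, 0.14, thus lay above all 4 column comparisons. On chromosome XIII the 20 neighbouring genes from YMR244W to SAP30, a run chosen after the values were seen and named by its ends, had the highest median relative to genes of the same length, 1.24, and 23 of 1000 shuffles of gene order gave so high a run. Since the shuffles mixed genes of all chromosomes, the higher level of chromosome XIII as a whole is part of this number, and a separate local run is not shown. Of 39 expressed features that the table names as new, 16 were at least 2-fold higher and 4 lower in UV02_HG, and 1 of 16 ribosomal RNA features reached 1 FPKM, with a median of 0 in every column, which does not measure the ribosomal RNA of the cells.

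The strain ratio falls with coding length, and so does the ratio of MF02 column 1 over column 2, with a rho of 0.62 for column 2 over column 1, so a length bias of RNA or library preparation that differs between libraries may account for much of it. The tables argue against short abundant genes as the source, since rho was -0.35 without ribosomal protein genes among genes of below-median expression, and against GC content, since rho stayed at -0.55 once its trend was removed. For UV02_HG RNA mixed into MF02 column 1, 8 genes with at most 3 reads in MF02 column 2 stood in column 1 at a median of 15.3% of their UV02_HG level, above the 10% set for mixing, but this decides nothing, since genes picked for a low column 2 favour column 1. Looks at the same 8 genes added after that result was seen found 3 of them (EMA17, AIF1 and COS10) under 1%, against one share for every gene, and 8 of 8 below 62.7%, the least share that would give the column difference of genes over 5000 nt, which argues against mixing as its main source. The length bias and a difference in RNA between the cultures, which was not tested, stay open.

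The thiamine genes are lower by far more than the length trend gives, with a median of -2.14 relative to genes of the same length. Reads shared among THI5, THI11, THI12 and THI13 do not account for it either. The 20 other members had a median of -1.60 relative to genes of the same length (SD 1.48 over genes), 13 of them below -1. These members still include near-identical copies such as SNZ2 and SNZ3. With near-identical copies summed, the list's raw median stayed at percentile 0 of lists matched on expression. That setting was not run relative to length. A candidate explanation is a difference between the strains in thiamine supply or regulation. With 1 sample per strain, it cannot be told apart from a difference between single cultures, such as in their medium.

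Chromosome XIII is higher in UV02_HG beyond the length trend, with a lowest value of 0.36 over the 4 column comparisons, and beyond GC content, with 0.34 after both trends were removed. A few clusters of neighbouring genes do not account for it, since the lowest of 15 blocks had a median of 0.18. A copy number difference of the whole chromosome may account for it, since both arms, 4 classes of expression and the shorter and longer genes all had medians of at least 0.30, with bootstrap SEs from 0.05 to 0.14. For comparison, 4 copies against 3 would give 0.42 and 3 against 2 would give 0.58. More copies in UV02_HG and fewer in MF02 give the same ratio, and DNA was not analysed here.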
